A study of Homo sapiens with 3 samples.

How the data were processed

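RNA was measured in human embryonic stem cells of the established line H1 that had been induced towards trophoblast-like cells with BAP and collected on day 9. The series holds 3 libraries, which are 1 library of wild type cells and 1 library from each of 2 TEAD4 knockout clones. Total RNA was made into libraries with a stranded kit, per the labels' protocols. The submitters' processing notes name cutadapt 1.14, HISAT2 2.0.5 and the human genome build hg19/GRCh37, without giving their roles. The tool that counted reads, its strand setting, the gene annotation and any filter on genes are not given in the sources used here.

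The authors deposited 1 table of whole-number read counts per gene symbol, with 1 column per library and no normalisation. It held 21999 symbols, 25 of which had been turned into calendar dates by a spreadsheet and were kept as they stood. The total count was 33658532 in the wild type, 30870789 in clone 1 and 31352153 in clone 2. A floor of 3 counts, the most that an unseen transcript may hide, corresponds to between 0.0871 and 0.0977 CPM. Such floors cover counting error only, since reads without molecular identifiers are not independent molecules.

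From these counts the following was computed. In R 4.3.3, edgeR 4.0.16 removed 4768 genes with low counts (filterByExpr by group), left 17231 genes for testing, and scaled the libraries by TMM. CPM values, which are counts scaled to a common library total, are given on that scale. The comparison of knockout with wild type used edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment and a threshold of 0.05. With 1 wild type library and 2 clones the fit has 1 residual degree of freedom, which comes from the difference between the clones, and 2.97 prior degrees of freedom. The wild type library is assumed to vary as the clones do. Nothing in the labels says whether the libraries came from cultures grown side by side, so the p-values measure only the spread between these samples. An adjusted p printed for a single gene is from this test unless another tool is named.

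The 31 gene lists, for trophoblast subtypes, TEAD and YAP biology, other lineages, signalling, cell cycle, stress and RNA quality, were fixed before the data were examined. The 30 lists with at least 5 tested members were compared with all other genes by camera in limma 3.58.1, on log2 CPM with a prior count of 2 and a preset inter-gene correlation of 0.01. Camera was also run with an estimated correlation. With 3 libraries that setting rests on 1 residual degree of freedom. A list that fails there has not been shown to owe its call to correlated genes. For each list, genes past the threshold were counted over all tested genes and adjusted over the list alone. Sizes were described without a test as the number of genes at least 2-fold from the wild type in both clones. The clones share the 1 wild type library, so that number was also simulated 100 times for unchanged libraries. All 3 simulated libraries took their mean and spread from the clones. Differences between the clones have no replicate. For them, a list's median was placed among 10000 random lists matched on mean expression.

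The genes named were also chosen by a rule fixed before the data were examined. TEAD4, CDX2 and GATA3 are named whatever their values. Then come up to 10 genes in each direction that pass the threshold, have at least 10 CPM in every library of the higher group and lie at least 2-fold from the wild type in both clones. Free places go to genes that fail only the adjusted p, ranked by the smaller of the 2 clones' changes. In each list, up to 4 passing members are named, or the 2 with the highest mean CPM where fewer than 2 pass. Between the clones, the 8 genes highest in each clone are named, among genes with at least 20 CPM in the higher clone. Other members of a list are given as examples, chosen after their values were seen. Genes such as the CGB family and HBA1 and HBA2 have near-identical copies and may share reads, so their single values are uncertain.

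The tests were tried on simulated data drawn for the 17231 genes of this comparison, with 200 genes changed, in 5 simulations. The quasi-likelihood test recovered 0% of genes changed 1.5-fold, 4% of those changed 2-fold, 39.2% at 4-fold and 58.8% at 8-fold, and 15.3% of its calls were false. DESeq2 1.42.0 recovered 4%, 36.8%, 64.8% and 78.8%, with 45.3% of its calls false. Limma-voom recovered 0%, 2%, 38% and 56.4%, with 11.1% false.

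The alternatives were other scaling factors (RLE, upper quartile, library size only), other filters on low counts, DESeq2, limma-voom, robust empirical Bayes, other thresholds and prior counts, the estimated correlation, list members at 5 CPM or more, and each clone left out. Alternatives chosen after seeing the data were a threshold of 0.1, removal of a trend with transcript length and GC content by natural splines with 4 degrees of freedom each, the same genes without that removal, and leaving out genes of cancer sequencing panels. Transcript length, GC content, chromosome and gene order came from a GENCODE annotation of GRCh38 matched by symbol. That build is not the one named for the files, so no coordinates are given. A transcript was found for 85.7% of the tested genes and 99.8% of the listed ones. Figures were drawn with matplotlib. Y-linked genes and the X-inactivation transcripts were left out when genes were named. They were not removed before the tests, so counts over all tested genes include any that passed the filter on low counts.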

Results

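Gene expression was compared between H1 human embryonic stem cells and 2 TEAD4 knockout clones after 9 days of trophoblast induction with BAP. BAP is a combination of BMP4 with inhibitors of activin and FGF signalling, and it drives pluripotent cells towards trophoblast-like fates. TEAD4 is a DNA-binding partner of the Hippo pathway coactivators YAP and TAZ and is needed for trophectoderm in the mouse embryo. The series names TEAD4 together with CDX2 and GATA3, and the comparison asks which transcripts differ at day 9 when TEAD4 has been knocked out. Effects of editing, cloning or culture that the clones share cannot be told apart from those of the knockout. The wild type was represented by 1 library and the knockout by 1 library from each of 2 clones. The total count lay between 30870789 and 33658532 per library, and between 19988 and 20287 genes had at least 1 read. The clones were not the same library deposited again, since the chi-square of their counts was 27.1 times its degrees of freedom, against 67.1 and 61.9 for each clone with the wild type. Across genes, which are not independent replicates, Spearman's rho was 0.993 between the clones and 0.983 between each clone and the wild type.

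TEAD4 transcript was present at similar levels in the 3 libraries. It had 615 reads (17.8 CPM) in the wild type, 628 reads (20.4 CPM) in clone 1 and 501 reads (16.3 CPM) in clone 2. The log2 fold change was 0.04 (SE 0.18, adjusted p = 0.909), and it was −0.01 when libraries were scaled by their size only and 0.34 after removal of the length and GC trend (adjusted p = 0.310). The edit is not described in the sources used here. A small edit can remove a protein and leave its transcript, so gene-level counts do not check the knockout labels, which are taken as given in what follows. CDX2, an early trophectoderm factor, was near the limit of detection, with 7 reads in the wild type, 1 in clone 1 and 2 in clone 2, and was not tested. GATA3, a trophoblast factor that BMP signalling induces, was at 335 CPM in the wild type and 345 CPM (331 and 359 CPM) in the knockout clones (log2 fold change 0.04, SE 0.09, adjusted p = 0.817). Its log2 fold change was −0.01 with library size only.

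The 10 genes named as furthest above the wild type in the clones labelled knockout include FOS, EGR1 and FOSB, which are immediate early genes, and CTGF. The transcription factor gene FOS was at 127 CPM in the wild type and 889 CPM ± 32.7 (SD, n = 2) in the clones, a 6.98-fold difference (adjusted p = 0.0908). EGR1 was at 97.4 and 525 CPM ± 47.4, FOSB at 4.35 and 47.1 CPM ± 7.48, and the ERK phosphatase gene DUSP1 at 18.9 and 128 CPM ± 17.7. CTGF, the matricellular gene used as a readout of YAP and TEAD, was at 260 and 1130.4 CPM ± 18.9, or 4.34-fold higher. VMP1, an autophagy gene, was 4.55-fold higher, EDN1, which encodes endothelin 1, 3.85-fold, ID4, an inhibitor of basic helix-loop-helix factors, 3.93-fold and XIRP1 4.63-fold. The unnamed locus CTD-2033D15.2 had 43 reads in the wild type, 1257 in clone 1 and 911 in clone 2. None of these 10 passed the threshold of 0.05; their adjusted p lay between 0.0908 and 0.113.

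The 10 genes named as furthest below the wild type include the placental hormone genes CGA, CGB5 and CGB1. CGA, the common alpha subunit of the glycoprotein hormones, was at 683 CPM in the wild type and 149 CPM ± 21.3 (SD, n = 2) in the clones, 4.57-fold lower (adjusted p = 0.0908). PGF, the placental growth factor gene, was at 63.4 and 9.32 CPM ± 1.37, or 6.80-fold lower. The chorionic gonadotropin beta genes CGB5 and CGB1 were 6.31-fold and 5.01-fold lower; their sequences are nearly identical, so how reads fell between them is uncertain. PHLDA2, an imprinted gene that restrains placental growth, was 5.09-fold lower. SUSD2 was 7.19-fold lower, DACT2 5.20-fold, TCL1B 5.06-fold, the sulfate transporter gene SLC13A4 4.14-fold and the endothelial cadherin gene CDH5 4.28-fold. None of these 10 passed the threshold; their adjusted p lay between 0.0908 and 0.109.

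**Figure D1:**
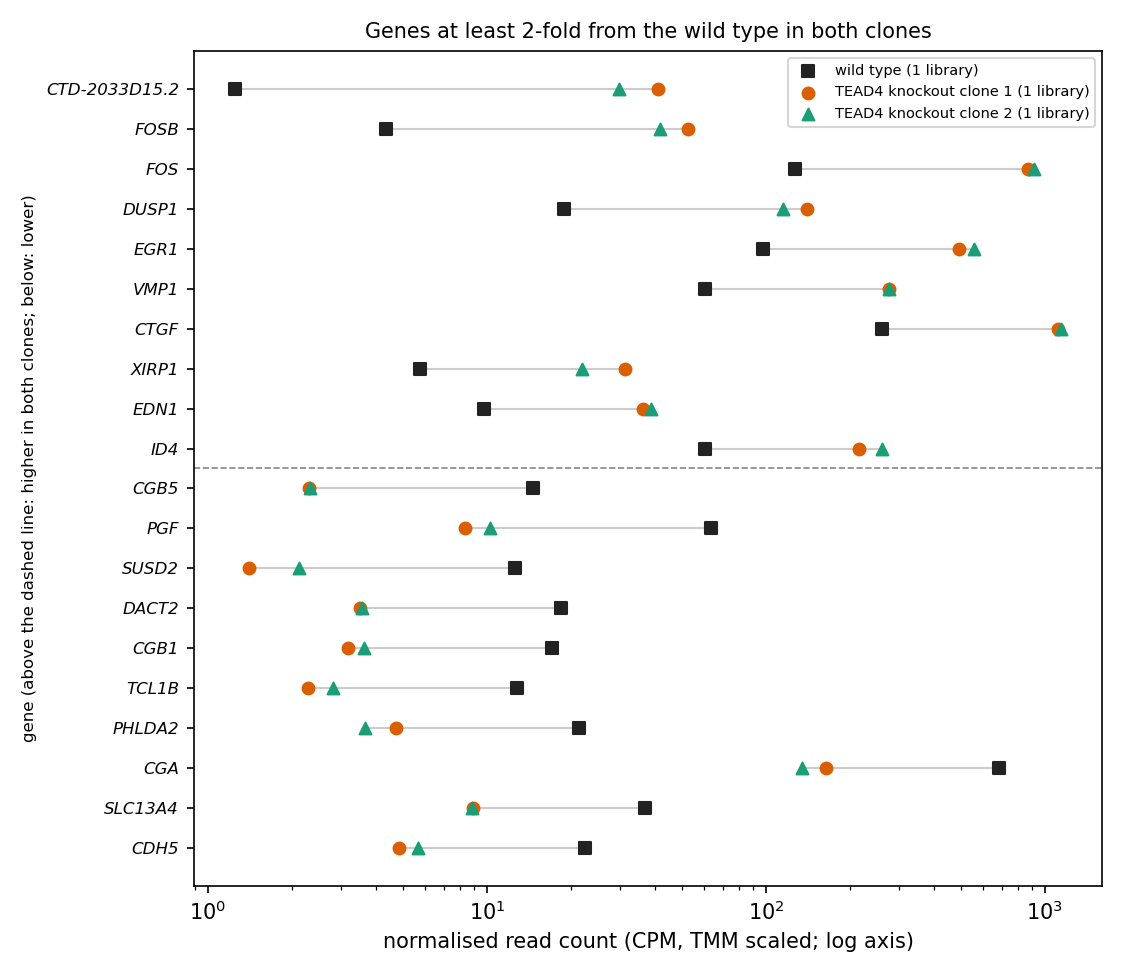
Normalised read count (CPM, log axis) of the 10 genes named as higher and the 10 named as lower in both clones, with 1 point per library (square, wild type; circle, clone 1; triangle, clone 2). In each gene both clones lie on the same side of the wild type, as for FOS (127, 866 and 912 CPM) and CGA (683, 164 and 134 CPM).

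Across 17231 genes, edgeR's quasi-likelihood test placed 0 genes higher and 0 lower in the knockout, with a smallest adjusted p of 0.0908. At an unadjusted p under 0.05 it placed 1935 genes higher and 1888 lower, where chance alone gives 431 each way. Limma-voom also called 0 and 0, with 1836 and 1986 at an unadjusted p under 0.05, while DESeq2 called 480 higher and 437 lower. The count depended on settings within edgeR as well, reaching 1078 higher and 1037 lower with robust empirical Bayes and 807 and 699 among genes with at least 1 CPM in 2 libraries. All 20 genes named above passed in both of those fits and in DESeq2. By size alone, 364 genes were at least 2-fold higher in both clones and 593 at least 2-fold lower. Unchanged libraries that share the 1 wild type gave means of 134.65 and 86.3 in simulation, and independent lists would overlap by 26.0 and 61.9 genes. The simulated wild type took its mean and spread from the clones. Genes that passed the filter through the wild type alone had means near 0 there, so the simulated number of lower genes may be too small. Among the 11037 genes with a mean of at least 5 CPM the numbers were 80 higher and 70 lower, against simulated means of 1.42 and 0.85. Part of the excess may come from the shared wild type library, which could not be split. The wild type library also held reads of 46 genes that were nearly unread in both clones. Leaving out 290 tested genes of cancer sequencing panels lowered the 593 to 545. Of those 290, 48 were at least 2-fold lower in both clones and 0 at least 2-fold higher. Only 15 of the 46 are on that panel list, so 545 does not bound the number lowered through such reads.

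Syncytiotrophoblast and hormone genes fell as a group. Of 31 tested members, 24 were lower in both clones and 4 higher, with a median log2 fold change of −1.33 (SD over genes 1.08; camera, adjusted p = 3.2e-08, and adjusted p = 0.847 with an estimated correlation). No member passed over all genes, and 23 lower and 3 higher passed when adjusted over the list alone. The list holds the fusogenic envelope genes ERVW-1 (syncytin-1; 46.5 CPM in the wild type, 13.0 ± 2.00 in the clones, SD, n = 2) and ERVFRD-1 (syncytin-2; 25.5 and 7.13 CPM), and the steroid synthesis genes CYP11A1 (46.4 and 12.8 CPM) and CYP19A1 (30.8 and 9.99 CPM). GCM1, a driver of trophoblast fusion, was at 4.76 and 1.27 CPM. PAPPA2, a protease gene with the highest level in the list, was at 1008 and 1060.2 CPM ± 235, a log2 fold change of 0.07 (SE 0.22, adjusted p = 0.870), and −0.04 after removal of the length and GC trend. ADM and PAPPA were the other way, at 9.58 and 22.03 CPM in the wild type and 20.6 and 44.4 CPM in the clones. In the same libraries, cytosolic ribosomal protein genes were also lower in the clones, with a median of −0.36, and −0.23 after removal of that trend. Of 10 pregnancy-specific glycoprotein genes listed, 2 were in the file and 0 had enough reads to be tested.

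Extravillous trophoblast markers divided. Of 20 tested members, 12 were lower and 4 higher in both clones, with a median log2 fold change of −0.29 (camera, adjusted p = 0.0269, and 0.847 with an estimated correlation). Adjusted over the list alone, 8 were lower and 2 higher. HLA-G, the class I molecule of invasive trophoblast, was at 3.83 CPM in the wild type and 1.37 CPM in the clones, and AOC1 at 4.24 and 0.602 CPM. FN1, which encodes fibronectin, was at 1383 and 2635 CPM ± 326 (SD, n = 2, adjusted p = 0.119). The matrix protease gene MMP2 was at 620 and 622 CPM (log2 fold change 0.01, adjusted p = 0.977), and its sign turned with upper quartile scaling, library size only or the filter at 1 CPM. The group call rested on genes with few reads. It ended among members with a mean of at least 5 CPM (adjusted p = 0.823), with the filter at 1 CPM in 2 libraries (0.116) and without the panel genes (0.0638), of which FLT4 had 129 reads in the wild type, 8 in clone 1 and 2 in clone 2.

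The transcription factors of trophoblast and the markers of cytotrophoblast, the progenitor layer, did not move as groups. Of 21 tested factors, 7 were higher and 8 lower in both clones (median 0.04, mean −0.23, camera adjusted p = 0.605), and 1 higher and 6 lower passed when adjusted over the list alone. The most abundant were TFAP2A, at 365 CPM in the wild type and 412 CPM in the clones (adjusted p = 0.308), and NR2F2, at 338 and 420 CPM (adjusted p = 0.168). Lower values were seen for GATA2 (50.4 and 24.2 CPM), TFAP2C (49.4 and 27.7 CPM), DLX3 (25.1 and 10.2 CPM) and OVOL1 (12.7 and 5.42 CPM), while KLF5 was at 31.7 and 56.4 CPM. Of 18 cytotrophoblast markers, 8 were higher and 5 lower in both clones (median 0.05, camera adjusted p = 0.605). KRT8 and KRT18, the keratins of simple epithelia, had log2 fold changes of −0.16 and −0.17 (adjusted p = 0.414 and 0.397), and 0.05 and 0.07 after removal of the length and GC trend. EGFR was at 182 and 278 CPM.

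Targets of YAP and TEAD factors rose as a group. Of 23 tested, 19 were higher and 2 lower in both clones, with a median log2 fold change of 0.39 (SD over genes 0.59; camera, adjusted p = 6.7e-05, and adjusted p = 0.847 with an estimated correlation). Adjusted over the list alone, 12 were higher and 0 lower. Only 2 of the 23, CTGF and CYR61, were at least 2-fold higher in both clones. The list's median was 0.43 in clone 1 and 0.27 in clone 2. CYR61, a matricellular gene related to CTGF, was at 383 CPM in the wild type and 1335 CPM ± 20.1 (SD, n = 2) in the clones (adjusted p = 0.0908), and AMOTL2 was at 196 and 357 CPM ± 20.8. IGFBP3, the most abundant member, was at 2575 and 2628 CPM (adjusted p = 0.890), and its log2 fold change of 0.03 became −0.02 with library size only. The TEAD factors and their cofactors rose slightly, with 12 of 19 higher and 2 lower in both clones (median 0.13, camera adjusted p = 0.0255, and 0.847 with an estimated correlation). That median was 0.07 with library size only, and 0.19 without clone 2. The list shares AMOTL2 and LATS2 with the YAP/TEAD targets, so the calls of these lists are not independent. Within that list TEAD1 was at 47.5 and 84.9 CPM ± 1.24, VGLL3 at 143 and 224 CPM, YAP1 at 522 and 559 CPM (adjusted p = 0.611) and AMOT at 504 and 660 CPM (adjusted p = 0.242). Mitochondrially encoded genes were also higher in these libraries, with a median of 0.21 (adjusted p = 0.847 with an estimated correlation).

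Immediate early genes and heat shock genes, fixed as a single list, went opposite ways. All 11 immediate early members had log2 fold changes above 0, with a median of 1.52 (SD 1.19), and all 10 heat shock members had values below 0, with a median of −0.31 (SD 0.09). After removal of the length and GC trend, 8 heat shock members were below 0 and 2 above, with a median of −0.18. The list as a whole did not pass (median 0.02, camera adjusted p = 0.146), but passed after that removal (median 0.21, adjusted p = 0.0158). With an estimated correlation and no such removal its adjusted p was 0.847, and 8 members higher and 4 lower passed when adjusted over the list alone. ATF3 was at 136 CPM in the wild type and 445 CPM in the clones, and NR4A1 at 28.0 and 80.6 CPM. The chaperone genes HSPA8 and HSP90AA1 were at 1083 and 851 CPM (adjusted p = 0.190) and at 879 and 672 CPM (adjusted p = 0.176). The FGF and ERK response list, which shares FOS and EGR1, did not pass (median 0.14, camera adjusted p = 0.605).

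Proliferation genes fell. All 26 genes of G2 and M phase were lower in both clones, with a median log2 fold change of −0.75 (SD 0.23; camera, adjusted p = 3.5e-10, and adjusted p = 0.847 with an estimated correlation), and 24 were lower when adjusted over the list alone. The DNA topoisomerase gene TOP2A was at 221 CPM in the wild type and 133 CPM ± 18.3 (SD, n = 2) in the clones (adjusted p = 0.126), the spindle gene TPX2 at 224 and 116 CPM ± 25.7 (adjusted p = 0.138) and CDK1 at 87.5 and 42.9 CPM. Of 23 S phase genes, 18 were lower and 1 higher in both clones (median −0.32, camera adjusted p = 0.000498, and 0.847 with an estimated correlation), with 0 passing over the list alone. The median of that list was −0.26 in clone 1 and −0.49 in clone 2, the value that stands when clone 1 is left out. MCM4 was at 110 and 88.0 CPM (adjusted p = 0.169) and TYMS at 91.2 and 68.1 CPM (adjusted p = 0.183). All 31 cytosolic ribosomal protein genes were lower in both clones (median −0.36, camera adjusted p = 7.0e-09, and 0.847 with an estimated correlation), and their median was −0.23 after removal of the length and GC trend. RPL13A was at 2327 and 1862 CPM (adjusted p = 0.214) and RPLP0 at 2201 and 1833 CPM (adjusted p = 0.241). Of 13 mitochondrially encoded genes, 12 were higher in both clones (median 0.21, camera adjusted p = 0.0255, and 0.847 with an estimated correlation). All symbols that begin with MT-, which include others besides these 13, took 4.83% of counts in the wild type. They took 5.08% in clone 1 and 5.53% in clone 2. MT-CO1 had a log2 fold change of 0.26 (adjusted p = 0.336) and MT-ND4 of 0.12 (adjusted p = 0.573).

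Lists of unfolded protein and amino acid response genes and of interferon response genes passed towards lower values, though not every member was lower. Of 21 genes of the unfolded protein and amino acid responses, 17 were lower and 4 higher in both clones (median −0.41, camera adjusted p = 0.0117, and 0.847 with an estimated correlation), and 6 lower and 2 higher passed over the list alone. DDIT4 was at 133 CPM in the wild type and 48.0 CPM in the clones, ASNS, which makes asparagine, at 93.5 and 48.4 CPM, CALR at 1144 and 924 CPM (adjusted p = 0.193) and HSP90B1 at 955 and 867 CPM (adjusted p = 0.470). Of 24 interferon response genes, 20 were lower and 2 higher in both clones (median −0.42, camera adjusted p = 0.000498, and 0.847 with an estimated correlation), and 2 were lower over the list alone. The median was −0.29 after removal of the length and GC trend. IFI6 was at 28.5 and 8.02 CPM and IFITM3 at 163 and 106 CPM. HLA-C had a log2 fold change of −0.18 (adjusted p = 0.277), and 0.11 after removal of the length and GC trend. STAT2 was at 218 and 219 CPM (adjusted p = 0.990), with a sign that turned under 5 alternatives. The ribosomal protein genes were lower in the same libraries, with the median of −0.36, or −0.23 without the length and GC trend.

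**Figure D2:**
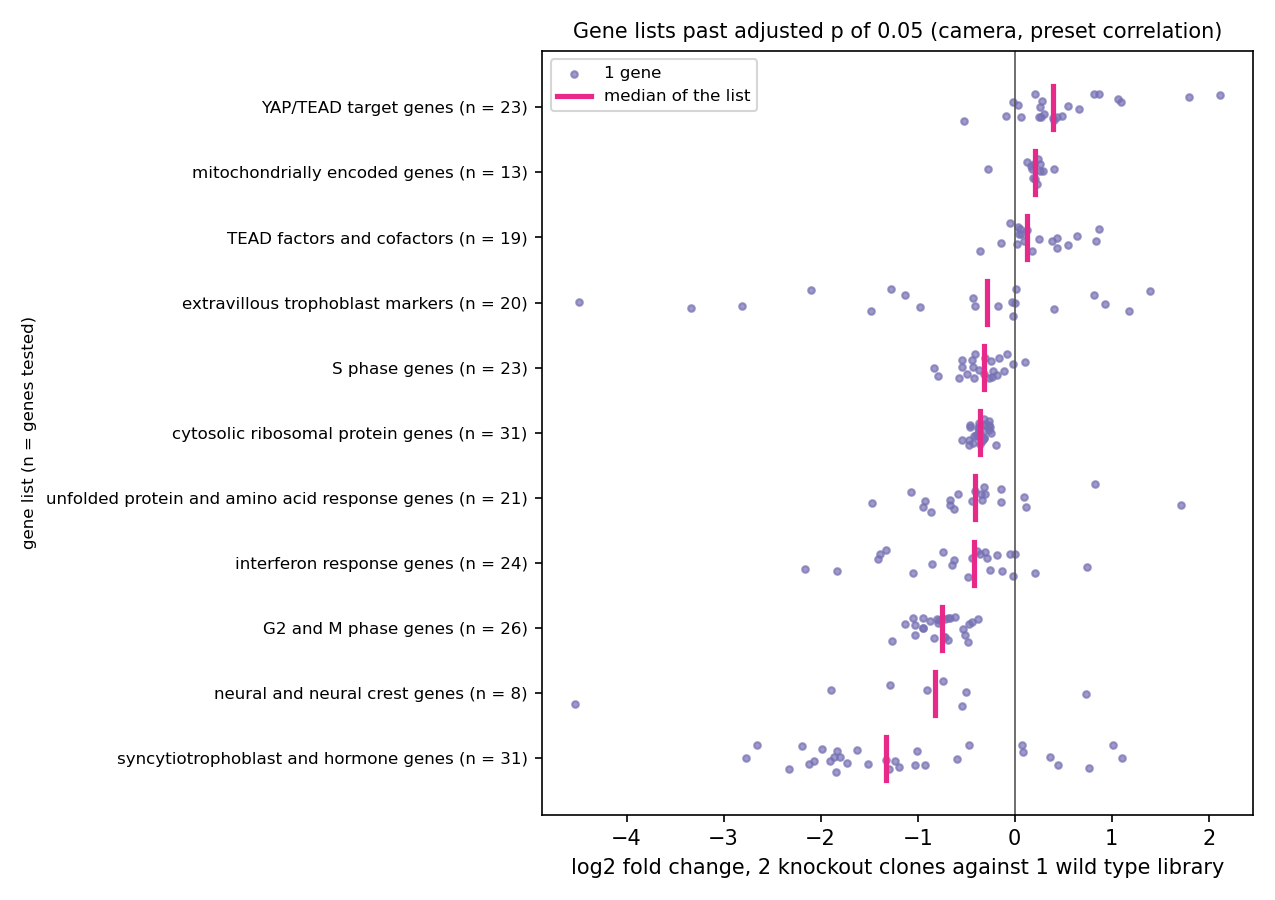
Log2 fold change of each tested gene (points) and the median (bar) for the 11 lists past an adjusted p of 0.05 by camera with a preset correlation, for 2 knockout clones against 1 wild type library; n is the number of genes tested. Medians run from −1.33 for syncytiotrophoblast and hormone genes to 0.39 for YAP/TEAD targets. No list passes with an estimated correlation (adjusted p = 0.847), but that setting rests on 1 residual degree of freedom.

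Markers of other fates were mostly low or unmoved as groups. Pluripotency genes did not pass (17 tested, 6 higher and 6 lower in both clones, median 0.03, camera adjusted p = 0.979). PODXL was at 276 CPM in the wild type and 305 CPM in the clones (adjusted p = 0.682), the RNA-binding gene LIN28B at 138 and 190 CPM (adjusted p = 0.130), and POU5F1 at 0.842 and 1.63 CPM. Amnion markers were abundant in the 3 libraries and did not pass (19 tested, 9 higher and 5 lower, median 0.18, camera adjusted p = 0.605). The amnion median was 0.11 in clone 1 and 0.07 in clone 2. GABRP was at 4143 and 5359 CPM (adjusted p = 0.173). Neural and neural crest genes fell, with 7 of 8 lower in both clones (median −0.82, camera adjusted p = 0.0111, and 0.847 with an estimated correlation). NES was at 156 and 107 CPM (adjusted p = 0.216) and STMN2 at 25.1 and 10.3 CPM (adjusted p = 0.109), while the other members lay under 5 CPM. The member SOX10 had 55 reads in the wild type, 4 in clone 1 and 0 in clone 2. It is 1 of the genes read in the wild type alone, and leaving out panel genes keeps it. The filter at 1 CPM in 2 libraries drops it and gave a median of −0.75 over 5 members. Mesoderm genes (11 tested, median −0.18, camera adjusted p = 0.237) and endoderm genes (8 tested, median −0.19, camera adjusted p = 0.673) did not pass. The medians of clone 1 and clone 2 alone were −0.34 and −0.26 for mesoderm genes and −0.0076 and −0.54 for endoderm genes. In these lists KDR was at 10.8 and 7.29 CPM (adjusted p = 0.193), FOXC1 at 9.78 and 8.85 CPM (adjusted p = 0.759), CLDN6 at 735 and 638 CPM (adjusted p = 0.304) and GATA6 at 1.83 and 1.87 CPM (adjusted p = 0.970). Endothelial and blood genes did not pass (14 tested, 6 higher and 7 lower, median −0.38, mean 0.60, camera adjusted p = 0.753), and their mean rests on fitted values of genes with 0 reads in a group. Their median was −0.08 in clone 1 and −0.77 in clone 2, and turned to 0.14 with the filter at 1 CPM and 0.50 without the panel genes. They include the globin gene HBA2, with 0 reads in the wild type, 153 in clone 1 and 137 in clone 2. Fibroblast and mesenchymal genes did not pass (23 tested, 13 higher and 5 lower, median 0.23, camera adjusted p = 0.356), with COL3A1 at 5515 and 9142 CPM (adjusted p = 0.144) and COL1A2 at 5407 and 7265 CPM (adjusted p = 0.193).

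The remaining lists did not pass in the main test. Basement membrane, integrin and matrix genes had 17 of 30 members higher and 6 lower in both clones (median 0.16, or 0.07 without clone 1; camera adjusted p = 0.125), with SPARC at 2841 CPM in the wild type and 2750 CPM in the clones (adjusted p = 0.864). Keratins and junction genes had a median of 0.05 (26 tested, adjusted p = 0.813), and p53 targets a median of −0.29 (17 tested, adjusted p = 0.113), or −0.06 after removal of the length and GC trend, with CDKN1A at 466 and 438 CPM and MDM2 at 292 and 242 CPM. BMP response genes had a median of −0.06 (18 tested, adjusted p = 0.661), with NOG at 214 and 259 CPM, and WNT response genes a median of −0.22 (14 tested, adjusted p = 0.594), with SFRP1 at 2171 and 2382 CPM and WNT5A at 133 and 163 CPM. Hypoxia and glycolysis genes had a median of −0.06 and a mean of 0.09 (23 tested, adjusted p = 0.979), with GAPDH at 2549 and 2650 CPM and ENO1 at 489 and 399.8 CPM. Cholesterol synthesis genes had a median of 0.21 (22 tested, adjusted p = 0.1005) and passed after removal of the length and GC trend (median 0.29, adjusted p = 0.0158). With an estimated correlation and no such removal its adjusted p was 0.847. The list's median was 0.31 in clone 1 and 0.08 in clone 2 before the removal. FDFT1 was at 294 and 341 CPM and HMGCS1 at 227 and 346 CPM. Imprinted genes had a median of −0.06 (19 tested, adjusted p = 0.661), with CDKN1C at 204 and 90.8 CPM, and replication-dependent histone genes a median of 0.17 (6 tested, adjusted p = 0.443), with HIST2H2BE at 14.7 and 49.7 CPM and HIST1H2AC at 15.1 and 14.7 CPM.

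The 2 knockout clones were closer to each other than to the wild type among well-read genes. At a mean of at least 5 CPM, 30 genes differed at least 2-fold between the clones, against 254 between the wild type and clone 1 and 232 between the wild type and clone 2. Over all tested genes 956 differed at least 2-fold, with no replicate to check them. The imprinted noncoding RNA H19 differed most among the genes named, at 3425 CPM in the wild type, 8.29 CPM in clone 1 and 6511 CPM in clone 2. Its neighbour IGF2, the insulin-like growth factor 2 gene, was at 2489, 3028 and 1725 CPM. The mesenchymal factor gene TBX15 was 3.65-fold higher in clone 2 than in clone 1, RELN 2.68-fold, BRINP1 2.48-fold, LIN7A 2.20-fold, COL6A6 2.11-fold, FPGT 2.06-fold and ADRA1D 2.05-fold. In the other direction UCHL1 was 2.02-fold higher in clone 1, DYSF 2.00-fold, the cystine transporter gene SLC7A11 1.94-fold, PLAC8 1.88-fold, the oxytocin receptor gene OXTR 1.88-fold, MGLL 1.87-fold, SPP1 1.87-fold and MYL7 1.85-fold. By list, the median of clone 2 minus clone 1 was −0.30 for cholesterol synthesis, −0.23 for unfolded protein and amino acid response, −0.20 for G2 and M phase, −0.18 for S phase and −0.13 for hypoxia and glycolysis genes, each at percentile 0 of 10000 random lists matched on expression. It was 0.18 for fibroblast genes, at percentile 100. Close to the ends as well were YAP/TEAD targets (−0.12, percentile 0.02), mitochondrially encoded genes (0.14, percentile 99.85) and BMP response genes (0.16, percentile 99.67). These percentiles describe the 2 libraries, not the clones as a kind. The random lists draw genes singly, so a list whose members move together reaches the ends easily. All 30 tested lists were placed in this way.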

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

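The length and GC correction, its uncorrected gene set, the threshold of 0.1 and the removal of panel genes were chosen after seeing the data. Against 0 genes higher and 0 lower in the main test, RLE factors gave 75 and 105, upper quartile 382 and 534, library size only 636 and 1054, at least 1 CPM in 2 libraries 807 and 699, DESeq2 480 and 437, and robust empirical Bayes 1078 and 1037. Removal of the length and GC trend gave 257 and 244, its gene set uncorrected 23 and 23, and the threshold of 0.1 gave 19 and 18. Limma-voom, no filter on low counts and leaving out the panel genes gave 0 and 0, as stricter thresholds must. The prior degrees of freedom were 2.97 in the main test, 1.45 with no filter, 4.07 with RLE, 5.30 with upper quartile, 7.995 with the filter at 1 CPM, 9.09 with library size only and a median of 12.3 with robust estimation. Among the 7 edgeR fits compared, the 2 with the lowest values called 0 genes and the other 5 called genes; why a small change of scaling moves this value was not tested. DESeq2 and the fit at 1 CPM shared 803 calls, all in the same direction. Removal of the length and GC trend let 13 lists pass, the 2 gained being cholesterol synthesis and the immediate early and heat shock list (adjusted p = 0.0158 each). With an estimated correlation and no removal these 2 stood at 0.847 and 0 of the 11 lists passed. Every list's estimate rests on 1 residual degree of freedom. The syncytiotrophoblast list's estimate was −0.0065, under the preset 0.01, yet its unadjusted camera p rose from 3.2e-09 to 0.094. The loss of calls in that setting therefore need not come from correlation. The numbers of genes at least 2-fold from the wild type in both clones (957) and between clones (956) became 150 and 30 at a mean of at least 5 CPM, since fewer genes remain, and the second became 558 with a prior count of 5. With 1 clone left out, the first lay between 1650 and 1756, since only 1 clone then has to differ.

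Directions turned in the following results, none of which passed in either setting; the cause was not tested. With library size only, TEAD4 was −0.0090, GATA3 −0.010, IGFBP3 −0.023, MMP2 −0.046, GATA6 −0.020, STAT2 −0.050 and FPGT −0.036. STAT2 was −0.00057 with RLE factors and in DESeq2, −0.025 with upper quartile and −0.011 at 1 CPM. MMP2 was −0.021 with upper quartile and −0.0071 at 1 CPM, and FPGT −0.0070 with upper quartile. With limma-voom GATA6 was −0.0060, FPGT −0.073 and ADRA1D −0.0017. After the length and GC correction KRT8 was 0.054, KRT18 0.075, PAPPA2 −0.039, FOXC1 0.024, CLDN6 0.091, CDKN1A 0.18, HLA-C 0.11, H19 0.18, IGF2 0.069, HIST1H2AC 0.058 and FPGT −0.092, and the median of BMP response genes was 0.078. Camera's direction, which need not follow the median's sign, also turned for pluripotency genes after that correction (median 0.0083), for endoderm genes with no filter (median 0.090) and without panel genes (−0.25), for endothelial and blood genes at 1 CPM (0.14) and without panel genes (0.50), for hypoxia genes at 5 CPM or more (−0.081) and without panel genes (−0.057), and for mesoderm genes without panel genes (−0.16). Other medians crossed 0 while camera's direction stayed. That of the immediate early and heat shock list did so with upper quartile (−0.0080), library size only (−0.032), the filter at 1 CPM (−0.072), members at 5 CPM or more (−0.058) and without panel genes (−0.059). With library size only it also held for trophoblast factors (−0.011), cytotrophoblast markers (−0.0060), pluripotency genes (−0.022) and keratins and junction genes (−0.00093). With no filter the medians were −0.00088 for trophoblast factors and −0.096 for histone genes, at 5 CPM or more −0.0061 for pluripotency and 0.11 for WNT response genes, and without panel genes −0.012 for cytotrophoblast markers. After the length and GC correction they were 0.0070 for mesoderm, 0.028 for hypoxia and 0.060 for imprinted genes. Clones 1 and 2 alone gave opposite signs for H19 (−8.68 and 0.93), TBX15 (−1.72 and 0.15), TEAD4 (0.19 and −0.13) and others.

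Of the results of the named genes other than TEAD4 under the alternatives fixed before the data were examined, 671 kept direction and side of the threshold, 168 newly passed, 16 turned sign and 5 moved beyond the spread of the clones. The medians of 17 of the 19 lists that did not pass and of 2 of the 11 that did lay over 1.5 times from the main value, or on the other side of 0, in at least 1 clone alone. Of the list results, 258 were counted as unchanged, 13 were lost, 3 turned and 21 moved. With 1 clone left out, lists that had not passed were counted by their medians in the same way, whatever the sign. The 13 lost are the 11 with an estimated correlation and extravillous markers with 2 filters. No paired analysis was possible with 1 wild type library. Depth limits genes with few reads most, such as CDX2 with at most 7.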

Other observations

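The test for panel reads and that for heat shock were chosen after the results they bear on had been seen; the other tests were written down before. The genes of these paragraphs that are not named in the report were chosen after their values were seen.

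Globin transcripts were read in both clones and not in the wild type. HBA2 had 0 reads in the wild type, 153 in clone 1 and 137 in clone 2, HBG1 had 0, 68 and 56, HBG2 had 0, 56 and 43, and HBB had 0, 33 and 33. The hair keratin-associated gene KRTAP2-3 had 4 reads in the wild type, 73 in clone 1 and 61 in clone 2. Genes with reads in the wild type and 1 clone alone included ZNF502, with 76 reads in the wild type, 0 in clone 1 and 91 in clone 2. C9orf64 had 66, 285 and 2 reads.

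Some genes were read in the wild type library alone. With at most 5 reads in each other library and at least 50 in the library itself, there were 46 such genes in the wild type, 0 in clone 1 and 0 in clone 2, with a median of 78 reads. They include the kinase gene PIK3CG (221, 0 and 0 reads in wild type, clone 1 and clone 2), CD22 (159, 2 and 1), ROS1 (117, 0 and 0) and the hepatocyte factor gene HNF1A (115, 0 and 1), which belong to unrelated tissues. Of the 46, 15 are on a list of cancer sequencing panel genes, PIK3CG not among them; the list was written from memory after genes read in the wild type alone had been seen. A candidate explanation for those on the list is that reads of a panel library entered the wild type library. Of 20 genes on the list that had at most 5 reads in both clones and were not among the genes seen first, 40% had at least 30 reads in the wild type, against 1.47% of 3678 other such genes (Fisher's exact test, two-sided, p = 4.2e-10). With all 46 and the members of the gene lists left out as well, it was 3 of 13 against 38 of 3599 (Fisher's exact test, two-sided, p = 0.00036). Blood cells or their RNA are argued against, since abundant blood cell genes had a median of 4.5 reads in the wild type, with PTPRC at 11, TYROBP at 0 and CD74, which these cells express, at 1989. The source of the reads, the other 31 genes, and whether some of these genes were transcribed in the wild type cells stay open.

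Of 11 immediate early genes 10 were higher in both clones, and of 23 YAP/TEAD targets 19 were higher and 2 lower. A trend with transcript length and GC content as the whole cause is argued against. After its removal the immediate early median was 1.68 (SE of the mean over genes 0.35). The YAP/TEAD target list still passed (adjusted p = 0.000261, camera with a preset correlation). That call is lost with an estimated correlation (adjusted p = 0.847, uncorrected data), a setting that rests on 1 residual degree of freedom. Heat shock or protein stress of the clones at harvest is argued against too. The heat shock members had a median of −0.31, and of −0.18 after the trend was removed. The SE of their mean over genes was 0.03 and 0.05, and genes are not independent replicates. A difference in handling at harvest that induces immediate early genes without heat shock genes, and an effect of the knockout, both stay open. With 1 wild type library neither was tested. Whether such handling would also raise the YAP/TEAD targets cannot be told from these libraries.

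H19 was nearly absent in clone 1 and abundant in the other libraries. Loss of a chromosomal segment that lowers the genes around it is argued against. The 20 nearest tested genes had a median log2 difference of clone 2 minus clone 1 of 0.0097. The largest of the 20 differences was 0.27. Their mean was −0.13, with an SE of the mean over genes of 0.09. Gain or loss of the whole chromosome is argued against as well, with a median of −0.0070 over its genes. A deletion of the gene alone or of a segment that lowers none of these neighbours stays open. So do a change of its imprint and an effect of cloning, and none of these was tested. The knockout, which both clones share, does not separate them.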
